A study of Mus musculus with 6 samples.

How the data were processed

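RNA from whole lung of 3 wild-type and 3 Falcor-null mouse samples, all after naphthalene and all with the same mixed strain label, was hybridised to single-channel arrays with biotin-labelled target, per the labels. Total RNA had been extracted with Trizol, column-purified with DNase treatment and amplified by in vitro transcription, per the labels' protocols. The deposited values are log2 signals per probe set, 1 column per array, and the submitters' processing notes name oligo, RMA and limma without versions. RMA corrects background, makes the arrays' distributions alike by quantile normalization and summarises the probes of a set, so that a shift of most genes in 1 direction would be removed and small differences near the ends of the scale are compressed. Whether rows were filtered, and which build of the genome the annotation used, is not given in the sources used here, and no coordinates are printed. The table held 24173 probe sets with values between 2.09 and 13.9. No detection calls were used here, so that signal over background is unknown for single probe sets.

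Genes were named through the platform annotation given with the series. Of the probe sets, 17476 had exactly 1 gene symbol and were used, 1308 had several symbols and 5389 had none in that table; both of these were left out of the main test. Of the used probe sets, 17368 had a gene number present in a RefSeq gene table of assembly GRCm38.p6, which served only for names and for the order of neighbouring genes. For the 740 genes with several probe sets, the one with the highest mean over the 6 arrays stood for the gene, which left 16537 genes. Falcor is listed there under the symbol 9030622O22Rik.

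Groups and replicate numbers were taken from the sample titles. Arrays labelled Falcor-null were compared with wild type by a linear model per gene with moderated variance (lmFit and eBayes in limma 3.58.1, R 4.3.3), two-sided, with no covariate, and p-values were adjusted over the 16537 genes by the Benjamini-Hochberg method. A gene passed at an adjusted p under 0.05. With 3 arrays against 3, an exact permutation test of 1 gene cannot go below 0.1, so the model that shares variance across genes carries the gene results. Differences are log2 Falcor-null minus wild type. Intervals of list means are 95% intervals from the spread of the 6 arrays.

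In all, 32 gene lists of cell types, pathways and tissues were fixed before the data were examined, and the 30 with at least 3 measured members other than the sex-linked list were tested with camera at its preset inter-gene correlation of 0.01, adjusted over the 30 lists. Of the 447 list genes measured, 12 stood in more than 1 list. Camera with an estimated correlation and fry were run beside it. Camera compares the list with the other genes, whereas fry's directional test asks whether a list's genes move, on balance, one way and compares with no other genes. Per list, the number of members passing over all genes and adjusted over the list alone was counted. After the data were seen, 9 further lists were added (lymph node, liver, regulatory and activated T cell, dendritic cell, mast cell and basophil, alveolar fibroblast, ribosomal protein, a second liver list and acute phase). These were adjusted over the 38 lists tested in all.

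The genes named were set by a rule fixed before the data were examined. They were Falcor, Foxa2 and 11 marker genes, then the 10 largest rises and the 10 largest falls among genes that passed and whose groups did not overlap, passing over microRNA, small RNA and olfactory genes and gene models without an official name, and up to 4 members with the smallest p in each list described. The kappa variable segments among them are given by probe set. Any other gene named was chosen after its values were seen, and the text says so.

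The scripts were tested on simulated data before use. In 16537 simulated genes with the spread of these arrays, the test of Falcor-null against wild type recovered 46% of genes changed by 0.5 on the log2 scale, 82% of those changed by 1, 98% of those changed by 2 and 96% of those changed by 3, with 9 false calls among 170 (5.29%). A list shifted by 0.5 was recovered in 20 of 20 draws, with 2 calls among 580 tests of lists that were not shifted. The simulated genes were drawn independently of one another, whereas the correlation estimated on these arrays reached 0.883 in the cell cycle list. These counts therefore do not give the list test's rate of false calls on these arrays.

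Alternatives fixed before the data were examined were the replicate number as a block, centring on array medians, a second quantile normalization, an intensity trend or robust variance in eBayes, array weights, leaving out dim probe sets below the 30th percentile or the median, testing every probe set, averaging a gene's probe sets, other thresholds, other list tests and leaving out each array in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.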

Results

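Gene expression was measured with microarrays in whole mouse lung after exposure to naphthalene, a compound that the airway's club cells turn into a toxic metabolite and that therefore injures the conducting airway. The 6 arrays fell into 2 groups of 3, wild type and Falcor-null by their labels, the latter a null genotype of the long non-coding RNA gene Falcor, which lies beside the transcription factor gene Foxa2. All 6 samples carried the same mixed CD1 and C57Bl6 strain label. The labels gave 28, 29 and 30 days after naphthalene for the wild-type samples and 31, 32 and 33 days for the Falcor-null samples, rising by 1 from each sample to the next, so that as the labels stand day and genotype changed together. Whether these are actual days, or a label that was raised by 1 from sample to sample, is not known here. The labels did not say whether the samples came from separate animals, and the p-values below measure only the spread between these samples, which may be technical. Each array gave log2 signals for 24173 probe sets, with medians between 6.69 and 6.74, and the number of arrays limits the precision. The median and the SD over probe sets were higher on every wild-type array than on any array labelled Falcor-null. The lowest value per array was 3.19 to 3.22 for wild type and 2.09 to 2.42 for the arrays labelled Falcor-null. Whether this difference between the groups is technical was not tested, and it cannot be separated from genotype here. Pearson correlations across probe sets, which are not independent replicates, lay between 0.982 and 0.986 for the 6 pairs of arrays within a group and between 0.970 and 0.976 for the 9 pairs of arrays from different groups.

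The comparison asked how lung labelled Falcor-null differs from wild type after naphthalene, and the targeted gene was read first as a check of the labels. The Falcor probe set (gene symbol 9030622O22Rik, probe set 17392549) was higher, not lower, on the arrays labelled Falcor-null. Its log2 signal was 5.05 ± 0.38 (SD, n = 3) on the wild-type arrays and 6.49 ± 0.28 (SD, n = 3) on the arrays labelled Falcor-null, a log2 difference of 1.44 (SE 0.21) or 2.72-fold, with an adjusted p of 0.0423 in limma. All 3 arrays labelled Falcor-null lay above all 3 wild-type arrays. Where this probe set lies relative to the altered part of the gene is not known here, and a probe set outside that part checks nothing. Every direction given below is that of the arrays labelled Falcor-null relative to wild type and rests on those labels. The Falcor call held with wild type replicate 3 left out and was lost with any other single array left out, with log2 differences of 1.26 without wild type replicate 1, 1.42 without wild type replicate 2, 1.28 without Falcor-null replicate 1, 1.52 without Falcor-null replicate 2 and 1.53 without Falcor-null replicate 3.

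Foxa2, the forkhead transcription factor of lung epithelium named in the series title as the gene under Falcor's control, gave 7.86 ± 0.03 on the wild-type arrays and 8.13 ± 0.07 on the arrays labelled Falcor-null (SD, n = 3 each; probe set 17392561). The log2 difference of 0.27 (SE 0.07), or 1.21-fold, had the arrays labelled Falcor-null higher in 3 of 3 but did not pass the test (limma adjusted p 0.175). Its relative Foxa1 differed by -0.04 on the log2 scale (adjusted p 0.883), the lung lineage factor Nkx2-1 by -0.05 (adjusted p 0.792) and the airway progenitor factor Sox2 by 0.09 (adjusted p 0.862). Among 17 measured genes of the list of Foxa2's chromosomal neighbours, 10 were higher and 7 lower, none passed the test over all genes or adjusted over the list alone, and the list had a mean log2 difference of 0.06 (camera adjusted p 0.237). Naa20 (0.27), Nkx2-2 (0.27) and Insm1 (0.20) had the smallest p-values of this list after Foxa2, with adjusted p-values of 0.298, 0.343 and 0.369.

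Immunoglobulin genes made up 9 of the 10 largest falls on the arrays labelled Falcor-null among genes that passed the test. Of 16537 genes tested, 92 passed an adjusted p of 0.05 in limma, 16 of them higher and 76 lower, and the fold changes of these genes ran from 1.40 to 20.8. Of those that passed, 29 lower and 4 higher genes differed by more than 2-fold. Jchain, the chain that joins secreted immunoglobulin A and M, had the smallest p and fell from 10.9 ± 0.12 to 8.14 ± 0.17 (SD, n = 3 each), 6.88-fold lower with an adjusted p of 0.000311. Ighm, the heavy chain of immunoglobulin M, was 6.10-fold lower (log2 difference -2.61, SE 0.21) by its brightest probe set. All 7 of its probe sets were lower, from -0.85 to -2.85, with a difference of -1.94 when averaged. Those at -0.85, -1.63 and -1.09 did not pass in limma over the used probe sets (adjusted p 0.491, 0.267 and 0.264). The kappa joining segment Igkj1 (6.54-fold lower), the heavy chain segment Igh-VS107 (4.80-fold) and 5 kappa variable segments also fell. The kappa variable segments, by their probe sets, were 17467435 (20.8-fold lower), 17467430 (13.4-fold), 17459324 (7.15-fold), 17467398 (5.32-fold) and 17459421 (4.59-fold). Such segments resemble one another in sequence, and signal cannot be assigned to 1 segment with certainty. Serpina1c, 1 of several near-identical genes for alpha-1 antitrypsin and uncertain for that reason, was 3.79-fold lower (log2 difference -1.92, SE 0.18, adjusted p 0.0115). Its relatives Serpina1b (0.17, adjusted p 0.724) and Serpina1e (0.06, adjusted p 0.925), picked after their values were seen, did not fall. They already read 5.11 and 5.56 on the wild-type arrays, near the 4.99 to which Serpina1c fell, where a fall could be hidden.

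The rises were fewer and smaller than the falls. The largest was in Nrcam, a neuronal cell adhesion molecule, from 6.31 ± 0.47 to 8.01 ± 0.30 (SD, n = 3 each; 3.25-fold, log2 difference 1.70, SE 0.25, adjusted p 0.0407). Ap4s1, a subunit of an adaptor complex for vesicle transport, rose 2.22-fold (log2 difference 1.15, SE 0.08, adjusted p 0.0035). The brighter of 2 probe sets annotated to Tpm3, a tropomyosin, rose 2.18-fold (adjusted p 0.00894). The other, dimmer one differed by 0.06 on the log2 scale, so a rise of Tpm3 itself is uncertain. The transcriptional repressor Bcl6b (1.90-fold), the glutamate receptor subunit Gria1 (1.88-fold), the endopeptidase Phex (1.78-fold), the proteoglycan Spock2 (1.76-fold), Tmtc2 (1.67-fold), the receptor phosphatase Ptprs (1.51-fold) and Gdf10 (1.49-fold), a growth factor of the TGF-beta family, rose as well. Their adjusted p-values lay between 0.0180 and 0.0477.

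**Figure D1:**
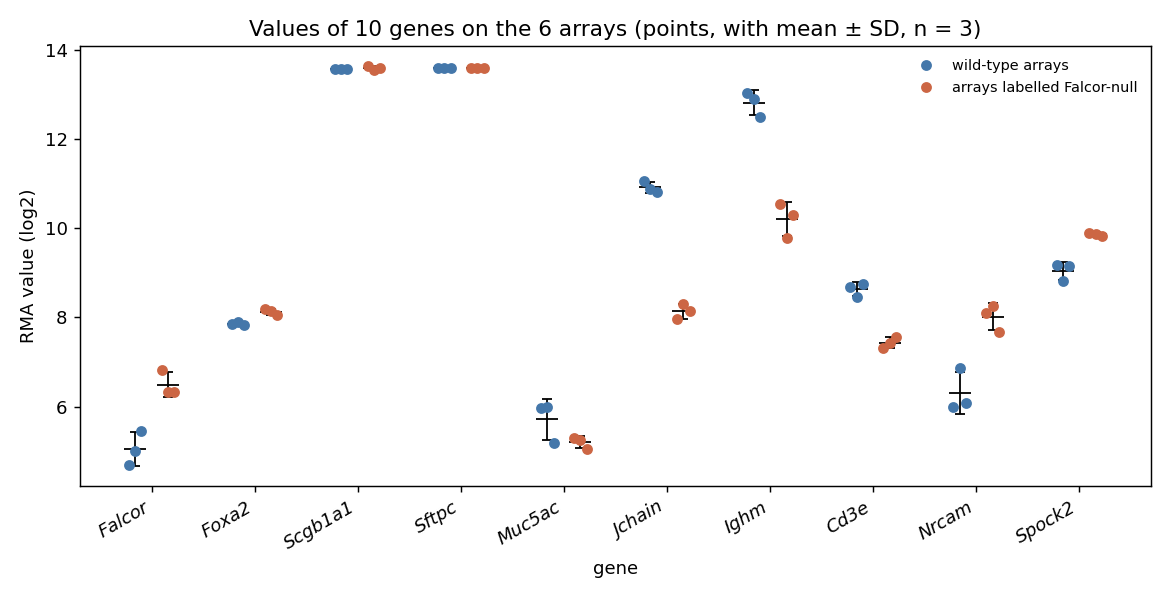
Log2 signal (vertical axis) of 10 named genes (horizontal axis) on each of the 6 arrays, as points coloured by group, with the mean and SD of each group of 3. Jchain and Ighm lie lower on all 3 arrays labelled Falcor-null than on any wild-type array, and Falcor lies higher on all 3.

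All 92 genes that passed had groups that did not overlap, as did 3230 of all 16537 genes (19.5%), where chance gives 10%. At an unadjusted p of 0.05, 2275 genes (13.8%) passed, 1010 higher and 1265 lower. The number of genes passing depended on single arrays: it was 26 without wild type replicate 2, 49 without wild type replicate 3, 24 without Falcor-null replicate 1, 18 without Falcor-null replicate 2 and 37 without Falcor-null replicate 3, against 89 without wild type replicate 1. Of Falcor and the 20 genes named for their rise or fall, 8 passed whichever array was left out. These were Jchain, Ighm, Igh-VS107, the kappa variable segments of probe sets 17467435, 17459324 and 17459421, Ap4s1 and, by its brighter probe set only, Tpm3. Igh-VS107 lost its call when a gene's probe sets were averaged (adjusted p 0.123), its second probe set differing by -2.38 with an adjusted p of 0.381, and Tpm3 lost its call with the replicate numbers as a block (adjusted p 0.0503).

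Markers of B and plasma cells fell together in camera with a preset correlation between genes (adjusted p 7.83e-14) and in fry (adjusted p 0.00522), with an adjusted p of 0.0877 in camera with an estimated correlation. All 14 measured members were lower, with a mean log2 difference of -0.82, 4 of them passed the test over all genes and 11 passed when adjusted over the list alone. Besides Jchain and Ighm, these were Mzb1, a chaperone of antibody-secreting cells (1.80-fold lower, adjusted p 0.0147), and Cd79a, part of the B cell receptor (1.68-fold lower, adjusted p 0.0282).

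T and NK cell markers fell as well in camera (adjusted p 3.5e-10) and fry (adjusted p 0.00897), with an adjusted p of 0.0877 with an estimated correlation. All 16 measured members were lower, with a mean log2 difference of -0.53, 3 passing over all genes and 8 adjusted over the list alone. Cd3e and Cd3g, parts of the T cell receptor complex, were 2.30-fold (adjusted p 0.00949) and 2.22-fold lower (adjusted p 0.0324), and the helper T cell coreceptor Cd4 was 2.34-fold lower (adjusted p 0.0131). Il7r, the interleukin 7 receptor, had a log2 difference of -1.21 that did not pass (adjusted p 0.0579). The thymus list had a mean log2 difference of -0.03 (camera adjusted p 0.935), with Themis at -0.33 (adjusted p 0.361). Only 4 of its 9 genes were measured, with wild-type means from 4.89 (Foxn1) to 5.73 (Cd1d1). The lowest mean of any probe set was 4.32, so the list is a weak check for thymus tissue.

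MHC class II genes, which present antigen to helper T cells, fell together in camera (adjusted p 1.43e-06) and fry (adjusted p 0.00522), with an adjusted p of 0.0877 with an estimated correlation. All 8 measured members were lower, with a mean log2 difference of -0.54. H2-Oa passed over all genes (1.66-fold lower, adjusted p 0.0327) and 5 members passed adjusted over the list alone, while H2-DMa (-0.52), H2-Ab1 (-0.42) and H2-DMb1 (-0.44) had adjusted p-values of 0.0845, 0.105 and 0.177. The class II gene H2-Ea, which is not in the list, is not expressed by C57BL mice and was picked after its values were seen, read 10.8, 3.99 and 6.26 on the wild-type arrays and 10.2, 10.2 and 6.48 on the arrays labelled Falcor-null.

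Alveolar macrophage markers fell in camera, with all 15 measured members lower and a mean log2 difference of -0.64 (adjusted p 2.75e-08). The list had an adjusted p of 0.294 with an estimated correlation and did not pass fry (adjusted p 0.106). None passed over all genes and 9 passed adjusted over the list alone. The chitinase-like protein Chil3 gave -1.12 (adjusted p 0.0748), Pparg, a regulator of this cell type, -0.50 (adjusted p 0.0854), the protease Ctsk -1.35 (adjusted p 0.123) and Plet1 -0.53 (adjusted p 0.165). Monocyte and interstitial macrophage markers also fell in camera (adjusted p 2.54e-06) and fry (adjusted p 0.0255), with an adjusted p of 0.111 with an estimated correlation. Of 14 measured, 12 were lower, with a mean log2 difference of -0.41, none passing over all genes and 8 adjusted over the list alone. Among them were the lipopolysaccharide receptor Cd14 at -0.69 (adjusted p 0.0791) and the complement genes C1qa (-0.48), C1qb (-0.48) and C1qc (-0.50), with adjusted p-values between 0.105 and 0.118.

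Neutrophil markers fell in camera (adjusted p 3.56e-05), with 10 of 11 lower and a mean log2 difference of -0.79. The list had an adjusted p of 0.305 with an estimated correlation and of 0.136 in fry. Its mean spread more between the wild-type arrays (SD 0.54) than between the arrays labelled Falcor-null (SD 0.17). None passed over all genes and 4 passed adjusted over the list alone. The protease genes Mmp9 (-0.85) and Mmp8 (-1.58), S100a8 (-1.41) and the growth factor receptor Csf3r (-0.88) had adjusted p-values between 0.133 and 0.237.

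The chemokines Ccl17 and Ccl22, which attract T cells through the receptor Ccr4, were 3.50-fold (adjusted p 0.0212) and 2.41-fold lower (adjusted p 0.0131). They were the only members of the type 2 inflammation list to pass, over all genes or adjusted over the list alone, and 10 of its 15 measured members were lower. Il33 gave -0.79 (adjusted p 0.272) and Clca1 -1.07 (adjusted p 0.277). The list fell in camera (mean log2 difference -0.38, median -0.06, adjusted p 0.0211) and passed fry (adjusted p 0.0398), but had an adjusted p of 0.213 with an estimated correlation, of 0.121 with camera on ranks and of 0.105 without wild type replicate 3. Among 17 measured interferon response genes 10 were higher and 7 lower, and the list did not pass (camera adjusted p 0.962, median 0.04, mean -0.02). Its member Bst2, a membrane protein that tethers virus particles, fell 1.73-fold (adjusted p 0.018) and was the only one to pass over all genes or adjusted over the list alone, while Zbp1 gave -0.48 (adjusted p 0.260), Ifih1 -0.21 (adjusted p 0.339) and Usp18 0.30 (adjusted p 0.352).

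In the airway epithelium, the club cell markers Scgb1a1 and Cyp2f2 differed by 0.02 (adjusted p 0.944) and 0.05 (adjusted p 0.859) on the log2 scale. Scgb1a1 read 13.6 in both groups, near the highest value on any array (13.9), where a difference can be compressed. Of 19 measured club cell genes, 7 were higher and 12 lower, with a mean log2 difference of -0.22 (camera adjusted p 0.264). Bpifa1, a secreted antimicrobial protein of the upper airway, fell 2.84-fold (adjusted p 0.0383) and was the only member to pass over all genes or adjusted over the list alone. The antimicrobial lectin Reg3g (-1.70), Scgb3a1 (-0.51) and Hp (0.13) had adjusted p-values of 0.303, 0.454 and 0.465. Without wild type replicate 3 the club cell list passed as lower (adjusted p 0.00346).

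Goblet cell genes fell in camera (adjusted p 0.00614), with 12 of 19 measured members lower and a mean log2 difference of -0.40. The list had an adjusted p of 0.294 with an estimated correlation and of 0.151 in fry, and with dim probe sets left out its camera adjusted p was 0.220. Itln1, a mucus-associated lectin, fell 2.47-fold (adjusted p 0.0265) and was the only member to pass over all genes or adjusted over the list alone, while Agr2 (-0.84), Slc26a4 (-1.16) and Tff2 (-1.21) had adjusted p-values between 0.207 and 0.265. The mucin genes Muc5ac and Muc5b gave log2 differences of -0.51 (adjusted p 0.361) and -0.69 (adjusted p 0.607). Muc5b read 9.78, 9.72 and 7.70 on the wild-type arrays, and without wild type replicate 3 its difference was -1.37 with an adjusted p of 0.0167.

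Ciliated cell genes divided evenly, 12 higher and 12 lower of 24, none passing over all genes or adjusted over the list alone, with a mean log2 difference of 0.04 (camera adjusted p 0.418, and 0.000696 as higher without wild type replicate 1). Their regulator Foxj1 gave 0.19 (adjusted p 0.699), Mcidas 0.36 (adjusted p 0.163), Cdhr3 -0.42 (adjusted p 0.274), Cfap43 0.29 (adjusted p 0.344) and Dnaic1 -0.34 (adjusted p 0.404). Basal cell genes had 5 higher and 2 lower of 7 measured, a mean log2 difference of 0.09 (camera adjusted p 0.237) and no member that passed, with Sostdc1 at 0.21 (adjusted p 0.281) and Trp63 at 0.19 (adjusted p 0.519). Krt5 had no probe set among those used and was not analysed here. Neuroendocrine genes had 4 higher and 6 lower of 10 and no member that passed, with a mean of -0.06 (camera adjusted p 0.935), Ddc at 0.18 (adjusted p 0.365) and Uchl1 at -0.25 (adjusted p 0.467).

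Genes of alveolar type 1 cells, the flat cells of the gas exchange surface, rose in camera (adjusted p 2.74e-06), with 15 of 17 measured members higher and a mean log2 difference of 0.27. The list had an adjusted p of 0.294 with an estimated correlation and of 0.0772 in fry. Spock2 passed over all genes and 4 members passed adjusted over the list alone. The growth factor gene Vegfa (0.38), Igfbp2 (1.13) and Sema3e (0.37) had adjusted p-values of 0.110, 0.134 and 0.155, and Ager, a standard marker of these cells, gave 0.24 (adjusted p 0.283). On the same arrays the B and plasma cell, T and NK cell and alveolar macrophage lists had means of -0.82, -0.53 and -0.64. Alveolar type 2 cell genes did not pass (8 higher and 11 lower of 19, mean -0.10, camera adjusted p 0.264, and 0.0440 as lower without wild type replicate 1). Sftpc, the surfactant protein C gene, read 13.6 in both groups, again near the highest value, and differed by 0.00 (adjusted p 0.993), while S100g gave -0.53 (adjusted p 0.175) and the surfactant gene Sftpd -0.47 (adjusted p 0.210).

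Lung epithelial transcription factors had 11 higher and 8 lower of 19 measured, none passing, with a camera adjusted p of 0.935. After Foxa2, Id2 (-0.33), Klf5 (0.26) and Ehf (-0.33) had the smallest p-values, with adjusted p-values of 0.233, 0.238 and 0.387. Epithelial junction genes had 15 higher and 9 lower of 24, none passing, with a mean of 0.04 (camera adjusted p 0.418, and 0.0356 as higher without Falcor-null replicate 3), Marveld2 at 0.34 (adjusted p 0.267) and Ocln at 0.25 (adjusted p 0.352). Epithelial-mesenchymal transition genes had 10 higher and 8 lower of 18, none passing over all genes and 2 lower ones passing adjusted over the list alone, S100a4 at -0.44 (adjusted p 0.118 over all genes) and Mmp9 at -0.85 (adjusted p 0.133 over all genes). The list had a camera adjusted p of 0.962, with Snai2 at 0.62 (adjusted p 0.229). For the transcription factor and the transition list the mean was below 0 (-0.00083 and -0.02), the median above 0 (0.03 and 0.02) and camera's direction upward. The interferon list differed in the same way between a mean below 0 and a median above 0, with camera's direction downward, as did the circadian clock list.

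Extracellular matrix genes (camera adjusted p 0.000202), smooth muscle genes (0.000239) and endothelial genes (0.000239) rose in camera on arrays where the leukocyte lists were lower. With an estimated correlation the adjusted p was 0.365 for matrix, 0.305 for smooth muscle and 0.140 for endothelial genes, and in fry 0.151, 0.110 and 0.0722. Extracellular matrix genes had 17 of 20 higher (mean log2 difference 0.23), with none passing over all genes and 1 adjusted over the list alone. The collagen genes Col6a3 (0.64) and Col6a1 (0.47), Sparc (0.24) and fibronectin Fn1 (0.28) had adjusted p-values of 0.0654, 0.253, 0.270 and 0.283. Smooth muscle genes had 12 of 13 higher (mean 0.24), with Tagln, an actin-binding protein, rising 1.46-fold (adjusted p 0.0407) as the 1 member that passed over all genes, 3 passing adjusted over the list alone, Mylk at 0.39 (adjusted p 0.131) and Tpm2 at 0.68 (adjusted p 0.177). Endothelial genes had 14 of 15 higher (mean 0.20), none passing over all genes and 3 adjusted over the list alone, with Cldn5 at 0.43, Tie1 at 0.47 and Egfl7 at 0.40 (adjusted p-values between 0.101 and 0.123). The B and plasma cell and T and NK cell means on these arrays were -0.82 and -0.53.

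The xenobiotic and glutathione list, which holds enzymes that process naphthalene and its products, had 12 higher and 12 lower of 24 and did not pass (mean log2 difference -0.09, camera adjusted p 0.418). Cyp1b1, a cytochrome P450, fell 1.56-fold (adjusted p 0.0276) as the 1 member passing over all genes, and 3 passed adjusted over the list alone. The oxidase Aox3 gave 0.49 (adjusted p 0.0653), the cystine transporter Slc7a11 -1.51 (adjusted p 0.0748) and Txnrd1 -0.21 (adjusted p 0.293). Cell cycle genes did not pass (12 higher and 8 lower of 20, none passing, mean 0.03, camera adjusted p 0.962), with Mcm5 at -0.20 and Pcna at -0.13 (adjusted p-values 0.549 and 0.560). Their list mean varied far more between the arrays labelled Falcor-null (SD 0.51) than between the wild-type arrays (SD 0.14), and without Falcor-null replicate 2 the list passed as lower (adjusted p 9.17e-06).

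Lists for tissue carried along in dissection and for the state of the samples were read beside these. Cardiac muscle genes, which vein walls in mouse lung also express, were higher in 14 of 15 and rose in camera (mean log2 difference 0.17, adjusted p 0.0006) and fry (adjusted p 0.0398), with an adjusted p of 0.177 with an estimated correlation. None passed over all genes or adjusted over the list alone, with Myh7 at 0.58 (adjusted p 0.131) and Tnni3 at 0.24 (adjusted p 0.256). Adipose genes had 6 of 8 lower and fell in camera (mean -0.18, adjusted p 0.0305), with an adjusted p of 0.421 with an estimated correlation and of 0.262 in fry. None passed over all genes and 1 adjusted over the list alone, with Pnpla2 at -0.46 (adjusted p 0.103). The adipose call was also lost with dim probe sets left out (adjusted p 0.127) and without wild type replicate 1 (adjusted p 0.362), wild type replicate 3 (0.0797), Falcor-null replicate 1 (0.143) or Falcor-null replicate 2 (0.106). Skeletal muscle (mean 0.07, adjusted p 0.310), circadian clock (mean -0.06, adjusted p 0.897) and immediate early genes (mean 0.14, adjusted p 0.0700) did not pass. The immediate early list passed as higher without Falcor-null replicate 3 (adjusted p 0.0320) and with the replicate numbers as a block (adjusted p 0.0350). Acta1 (0.16), Bhlhe41 (-0.70) and Ccn1 (0.53) had the smallest p-values of these 3 lists and adjusted p-values of 0.390, 0.228 and 0.256. Of the erythroid list only Fech (0.36, adjusted p 0.271) and Slc4a1 (0.31, adjusted p 0.771) were measured, too few for a test. Of the sex-linked list only Xist was measured, at 11.01 ± 0.13 and 11.07 ± 0.01 (SD, n = 3 each).

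**Figure D2:**
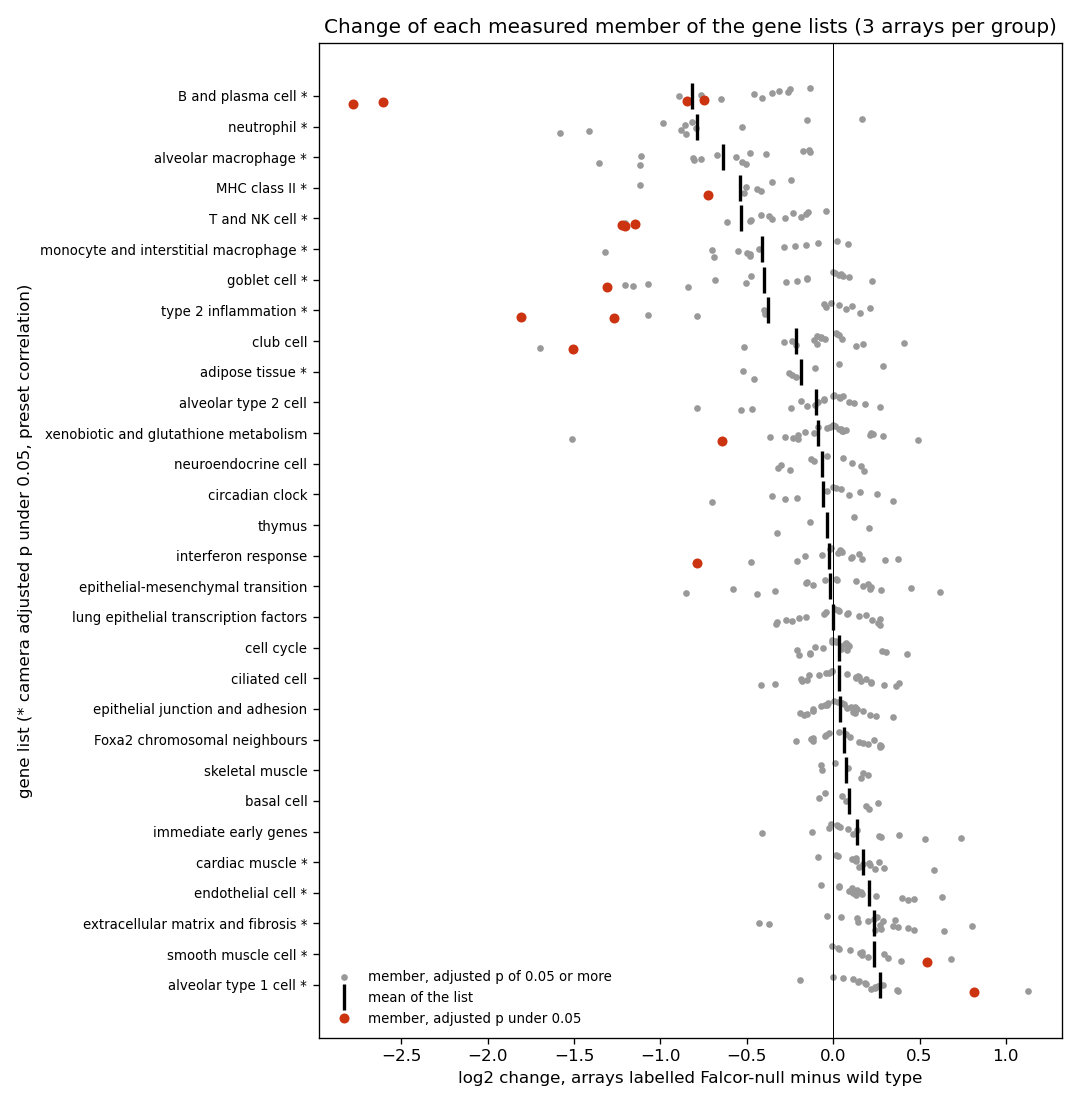
Log2 change of each measured member of the 30 tested gene lists (horizontal axis, arrays labelled Falcor-null minus wild type), with 1 list per line, the list mean as a bar, members with an adjusted p under 0.05 in red and an asterisk for lists with a camera adjusted p under 0.05 at the preset correlation. All measured B and plasma cell, T and NK cell, MHC class II and alveolar macrophage genes lie below 0, and 15 of 17 alveolar type 1 cell genes lie above it.

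Of the 30 lists tested, 14 passed camera with its preset correlation, 9 lower and 5 higher. None passed with an estimated correlation, where the lowest adjusted p was 0.0877 and 7 lists had an unadjusted p under 0.05, and 6 of the 14 passed fry's directional test, 5 lower (B and plasma cell, T and NK cell, MHC class II, monocyte and interstitial macrophage, type 2 inflammation) and 1 higher (cardiac muscle). Fry's mixed test, which counts movement in either direction and compares with no other genes, passed 16 of the 30 lists. Those that passed neither camera nor the directional test were Foxa2's neighbours (adjusted p 0.000863), transcription factors (0.00508), transition (0.00155), xenobiotic (0.000637) and interferon (0.000126). Of all genes 13.8% had an unadjusted p under 0.05, so the mixed test does not set these lists apart from other genes. One other division of the 6 arrays into 3 and 3 gave 16 lists, more than the 14 of the real groups, so that the number of lists called at the preset correlation does not by itself set the groups apart.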

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

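The number of arrays limits these results, and signal over background is unknown here. Centring on array medians, a second quantile normalization, an intensity trend, robust variance, array weights, leaving out dim probe sets and averaging probe sets gave 83 to 131 genes against 92, and the median log2 change of all genes was 0.0308 after centring and 0.0161 after the second normalization, against 0.00258. Larger differences came from testing every probe set (171 genes or unnamed probe sets), from an adjusted p under 0.10 (280), from an unadjusted p under 0.01 (822) and from an unadjusted p under 0.05 with a fold of at least 1.5 (415). The last 3 follow from a looser threshold. For testing every probe set the cause was not tested. With each array left out the count ran from 18 to 89, with 15 to 55 of the 92 genes still called and 0 changes of sign, and fewer samples enter each such fit. Over the arrays left out, Falcor lost its call 5 times, and the other named genes lost theirs 50 times and gained one 1 time (Muc5b). Genes with a call reversed 0 times, and named genes without a call changed sign 6 times. Camera with an estimated correlation called 0 of the lists and fry's directional test 6, against 14, and the other settings called 12 to 16. Among the 14 lists, the estimated correlation ran from -0.0436 (MHC class II) to 0.527 (alveolar macrophage), against the preset 0.01. A higher correlation makes camera stricter. MHC class II and type 2 inflammation (-0.0148) had estimates below the preset value and still lost their calls. The correlation therefore does not account for every loss. What else contributed, and the cause for fry and the other settings, was not tested.

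Falcor kept its direction under every setting that gave a value, from 1.26 to 1.64 with each array left out (adjusted p 0.0379 to 0.143), and had no value with probe sets above the median, which leaves it out. Foxa2 stayed higher and never had an adjusted p under 0.05 (0.0991 to 0.394), but its unadjusted p of 0.00719 passes the unadjusted threshold of 0.01. The cell cycle list turned from not passing to lower without Falcor-null replicate 2, with adjusted p-values from 9.17e-06 to 0.99 over the 6 arrays left out; the cause was not tested.

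The replicate numbers were tried as a block although nothing in the labels says that they pair samples. Deviations from the group means correlated at 0.022, -0.0025 and -0.081 between same-numbered arrays, so they share only a number. With the block 32 genes passed, Falcor's difference stayed at 1.44 with an adjusted p of 0.119, and 15 lists passed. The immediate early list was the one gained (camera adjusted p 0.0350, higher). Fewer residual degrees of freedom remain in that fit.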

Other observations

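The gene lists introduced in this part were added after the called genes had been seen, and of the tests below only those of the lymph node list, the second liver list and the division of arrays for the gene lists were set before their results were seen; the others were set after.

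The added regulatory and activated T cell, dendritic cell and alveolar fibroblast lists followed the 2 directions of the main lists. They hold called genes that had been seen beforehand, so their p-values are no independent evidence. Regulatory and activated T cell genes were lower in 12 of 12 measured (mean log2 difference -0.57, camera adjusted p 2e-09, 0.157 with an estimated correlation, fry 0.0275), with Icos 2.26-fold, Ctla4 1.92-fold and Il23r 1.67-fold lower past the threshold and Foxp3, the regulatory T cell factor, at -1.10 (adjusted p 0.0534). Dendritic cell genes were lower in 12 of 14 (mean -0.57, camera adjusted p 7.18e-07, 0.0837 with an estimated correlation, fry 0.0184), where Ccl17, Ccl22 and the costimulatory gene Cd80 (1.72-fold lower) passed and the first 2 also stand in the type 2 inflammation list. Alveolar fibroblast genes were higher in 11 of 12 (mean 0.35, camera adjusted p 2.15e-07, 0.157 with an estimated correlation, fry 0.0275), with Foxf1 (1.40-fold) and Gdf10 (1.49-fold) past the threshold. Immunoglobulin segments, with the heavy chain gene Ighm counted among them, were lower in 13 of 13. Of these, 8 were past the threshold, against 68 of 16524 other genes (Fisher's exact test p 1.72e-16, two-sided). That test was chosen after the falls were seen and over segments that resemble each other, so it is no independent evidence. Ribosomal protein genes had a mean of -0.08 (camera adjusted p 0.0712). Mast cell and basophil genes had 2 measured, Gata2 at -0.05 and Kit at 0.02.

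Several other called genes stand outside the lists and were picked after their values were seen. The B cell chemokine Cxcl13 was 2.91-fold lower (adjusted p 0.0147), the interferon-induced T cell chemokine Cxcl9 2.96-fold lower (adjusted p 0.0341), the inflammasome genes Casp1 and Aim2 1.71-fold and 1.73-fold lower, and the protease inhibitor Spink5 3.21-fold lower (adjusted p 0.0180). The alveolar type 1 minus type 2 list difference changed by 0.37 between the groups (95% interval 0.08 to 0.66, without overlap of the groups). It was computed after the list results were seen and restates them with an interval, and some type 2 genes read near the highest value, where a difference can be compressed, so it decides nothing about the cause of the higher lists.

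Some genes differed by more than 3 log2 units between arrays of 1 group, H2-Ea among them, and were picked after their values were seen. Gm3893 read 5.77, 6.06 and 9.81 on the wild-type arrays and 9.999, 9.74 and 10.2 on the arrays labelled Falcor-null (adjusted p 0.265). Cwc22 read 7.18, 7.18 and 7.07 against 10.4, 7.08 and 9.65 (adjusted p 0.320). All 6 samples carry a mixed strain label, and the share of each strain in each sample was not analysed here.

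The first pattern weighed is the higher Falcor signal on the arrays labelled Falcor-null. One array or pair with the other group's label is argued against by the arrays themselves, since the lowest correlation within a group exceeded the highest between groups by 0.00615. A stronger signal of the whole chromosomal segment is argued against by the 40 nearest measured genes, whose median log2 change was -0.0199 (quartiles -0.12 to 0.11), far below the 0.72 that 0.5 of Falcor's change comes to. An exchange of all labels cannot be told apart from a probe set that lies outside the altered part or reads a transcript made from the altered gene, since all 3 arrays labelled Falcor-null lay above all wild-type arrays and no other gene here marks the genotype.

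The second pattern is the fall of the leukocyte lists. Leukocyte genes (78) minus genes of the epithelial and stromal cell lists (143) changed in mean by -0.61 (95% interval -0.95 to -0.26). A shift of every gene by the same amount moves both alike and would leave this difference unchanged. Camera had already put these leukocyte lists below the other genes. The value therefore restates that result and is no separate test of such a shift. A straight trend over the days in the labels is argued against only if those are actual days, which is not known here, since 3 days of the trend within groups projected on the group difference with a factor of -0.33 (-0.42 and -0.24 in the 2 groups), where a cause needs 0.5 or more; a step between the groups' days cannot be told apart from genotype. Whether lymph node carried with the wild-type lungs accounts for part of the lymphocyte genes was not decided. The lymph node list changed by -0.20 (95% interval -0.50 to 0.11, 5 measured genes). This interval leaves out the T and NK cell list's -0.53 but reaches past 0.5 of it, the bound set for deciding against lymph node. Ccr7 (-0.61), also in the dendritic cell list, fell most, against Glycam1 (-0.27), Chst4 (-0.25), Madcam1 (-0.03) and Satb1 (0.17). The alveolar macrophage list's change of -0.64 (interval -1.22 to -0.05, 15 of 15 genes lower) runs against lymph node for that list, since lymph nodes express these genes little, but its interval reaches past 0.5 of the T and NK cell list's change, the bound set for it, and the neutrophil list's interval (-1.69 to 0.11) is wider. The genotype, as the design names it, remains an untested explanation.

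The third pattern is the fall of liver genes, noticed through Alb (2.86-fold lower), Serpina1c and Ttr (1.55-fold lower), so that the liver list is no independent evidence (14 of 18 lower, mean -0.67, camera adjusted p 4.21e-08, 0.0833 with an estimated correlation, fry 0.0044). Liver carried with the wild-type lungs cannot be told apart from a change in the lung. A second liver list, with 12 of 30 genes measured and 9 of these lower, changed by -0.29 (95% interval -0.55 to -0.04). Its median was -0.09, and Mup3 (-2.04) and Hamp (-1.04) set the mean. Apart from these and Mat1a, its members read from 4.49 (Apoa5) to 5.79 (Itih1) on the wild-type arrays, where a fall could be hidden. A lower acute-phase response of the lung is a candidate explanation, since the acute-phase list changed by -0.85 (interval -1.39 to -0.31, 10 of 11 lower), with Lbp at -1.11 (adjusted p 0.0791) and Lcn2 at -0.72 (adjusted p 0.0765). Cfb and Hp of that list had been seen beforehand, and without both the mean was -0.98 (interval -1.63 to -0.32). Liver also makes acute-phase proteins, so this value does not tell the 2 explanations apart.

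Of the 10 divisions of the 6 arrays into 3 and 3, too few for a share under 0.05, the real one called 92 genes and the highest of the others 0, so that 1 of 10 gave as many. For the gene lists the real division called 14 and the highest of the others 16, so that 2 of 10 gave as many. That other division set wild type replicates 1 and 2 with Falcor-null replicate 3 against the rest, and it called 0 genes.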
